A study of Mus musculus with 2 samples.

How the data were processed

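RNA was sequenced from primary hepatocytes of C57BL/6 mice, cells freed from the liver with collagenase and kept in culture. The cells had been infected overnight with an adenovirus carrying either β-galactosidase (β-Gal, a bacterial enzyme used as a control) or HuR, the RNA-binding protein encoded by Elavl1. There was 1 library per group, so 2 libraries in all, sequenced on an Illumina HiSeq X instrument per the labels. Groups were taken from the overexpression label of each sample.

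The authors deposited 1 table per library with 1 FPKM value per gene, a read count scaled by transcript length and library size. TopHat2, HTSeq 0.6.1 and the mouse genome build GRCm38 are named in the submitters' processing notes, without the order or role of each step. The annotation release, the way the FPKM values were calculated, the library kit, the strand setting and any filter on genes are not given in the sources used here. Without a strand setting, overlapping and antisense genes cannot be separated, and values of near-identical paralogs such as the Mup genes are uncertain.

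Both tables listed the same 20505 genes. None had a value of 0 in the β-Gal table, whereas 2233 (10.9%) were at 0 in the HuR table. Genes at 0 in the β-Gal library are therefore not analysed here, whatever their level in the HuR library. Any gene found only in the HuR library is missing from the higher calls and from the largest rises. Among the listed genes of lowest expression, the omission tilts values toward lower ones in the HuR library. Identifiers were matched to GENCODE mouse release M21 (GRCm38), which may differ from the release the authors used. A match was found for 20133 genes, while 272 entries had placeholder names and 100 other identifiers were not in that release.

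The FPKM values moved in steps that matched whole reads divided by the rounded mean transcript length of a gene and by a library total. The implied totals were 18357017 reads for β-Gal and 17671387 reads for HuR. With these totals, values in both libraries lay within 0.02 of a whole read for 14753 of the 20133 genes with a length (73.3%), and for 89.9% of genes with 1 annotated transcript. Reads of the other genes are estimates from GENCODE lengths. In a transcript of 2 kb, 1 read was worth 0.0272 FPKM in the β-Gal library and 0.0283 FPKM in the HuR library. Recovered reads were used for counting intervals, floors, shares of reads, minimum read numbers and sums over tissue markers, never for a count test.

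Fold changes were calculated as log2((HuR + 1)/(β-Gal + 1)) on FPKM, a scale that understates the change of genes of low expression. Ratios printed as a fold are ratios of the FPKM values without the pseudocount. Genes with at least 1 FPKM in either library were compared, which left 12905. A gene was called higher or lower when it differed by at least 2-fold on the log2 scale with the pseudocount. With 1 library per group there is no replicate check, no test between conditions and no p-value. Intervals beside a fold are 95% intervals from the exact Clopper-Pearson method on the share of a gene's reads in each library. They cover counting error only, and not differences between cultures, infections or library preparations. Where a gene had 0 reads in the HuR library, its fold was bounded against a floor of 3 reads per library. This bound takes the β-Gal reads as measured, so the counting interval, which includes their error, begins lower.

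The rule for naming genes was set before the data were examined. It took Elavl1, then the 12 largest differences in each direction among genes with at least 5 FPKM in a library. Predicted or unnamed models, pseudogenes and genes of under 200 bases were left out. From each gene list it took up to 4 members with the largest difference, or the most abundant members where a list differed little.

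The 36 gene lists were also fixed before the data were examined. The metabolic lists were oxidative phosphorylation, mitochondrially encoded genes, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation, lipoprotein assembly, bile acid synthesis and transport, gluconeogenesis and glycogen, glycolysis, urea cycle and amino acid catabolism, and drug metabolism. The lists of liver function and stress were hepatocyte identity, acute phase response, interferon response, NF-kB targets, immediate early genes, p53 targets and apoptosis, endoplasmic reticulum and amino acid stress, heat shock proteins, NRF2 targets, sex-biased liver genes and clock genes. The lists of RNA and protein machinery were mRNAs with reported HuR binding, AU-rich element binding proteins, cell cycle, ribosomal proteins, proteasome subunits, spliceosome and nuclear RNA-binding proteins, and matrix and cytoskeleton genes of cultured hepatocytes. Replication-dependent histones and nuclear-retained and non-coding RNAs were fixed as signs of differences in library preparation. Markers of stellate cells, Kupffer cells, endothelial cells, cholangiocytes, and lymphocytes with blood cells made up the remaining lists. Some genes belong to more than 1 list. Some members that the naming rule would take are not reported here.

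The median log2 fold change of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, with seed 1. Lists with fewer than 5 compared members received no percentile. A list under percentile 1 or over percentile 99 was described as standing apart, which describes these libraries only. A second set of random lists, added after the data had been seen, was matched on expression (5 classes), GC content (4 classes) and length (4 classes). Other alternatives changed the pseudocount, the expression minimum, the scaling, the threshold and the gene types. Those added after the data had been seen removed the trend of the fold change with GC content or length, set the median of all genes to 0, asked for 100 reads, or asked for a counting interval beyond 2-fold. Trend removal subtracted the median of each class, which also sets the median of all genes to 0, and was repeated with that median added back.

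The procedure was tested on simulated reads for 12678 genes of this comparison, of which 200 were changed. It called 93% of genes changed 3-fold and 99% of genes changed 8-fold in the right direction, and 42 unchanged genes (0.337%). The counting interval held the true fold for 95.7% of genes, and 3% of random lists fell beyond percentile 1 or 99. Both simulated libraries were drawn from the β-Gal reads with counting error only. These rates therefore leave out differences between cultures, infections or library preparations, and are not error rates of the calls between the 2 real libraries. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.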

Results

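Gene expression was measured by RNA sequencing in cultured primary mouse hepatocytes after overnight infection with an adenovirus carrying β-Gal or HuR. The comparison asks which transcripts differ when HuR, a protein that binds AU-rich and U-rich RNA, is overexpressed. Each group was a single library, with implied totals of 18357017 reads for β-Gal and 17671387 reads for HuR. No value below has a replicate. Intervals in parentheses are 95% counting intervals unless they are called bootstrap intervals. Gene expression in both libraries had a Spearman correlation of 0.94 across the compared genes, which are not independent replicates.

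Elavl1, the gene that encodes HuR, was far higher in the library labelled HuR, at 4480 FPKM against 9.67 FPKM in the β-Gal library. This was a 463-fold difference (428 to 503) and a log2 fold change of 8.71, the highest of any compared gene. Elavl1 (ENSMUSG00000040028) lies on the minus strand of chromosome 8 at 4285382 to 4325413 in GRCm38. Its transcripts went from rank 7266 to rank 10 by level, and from 0.00326% (0.00300 to 0.00353%) to 1.51% (1.504 to 1.515%) of reads. By comparison, albumin (Alb) took 2.28% of reads in the β-Gal library and 2.48% in the HuR library. The values do not separate transcripts of the virus from those of the chromosomal gene. The species and untranslated regions of the viral HuR insert are not given in the sources used here. The HuR level, fold and rank rest on the length of annotated Elavl1 transcripts and may therefore be mis-scaled. The share of reads was recovered with that annotated length, which cancels if the FPKM values were calculated with the same length.

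The HuR library had higher p53 target, heat shock, immediate early and Kupffer cell transcripts, and lower transcripts of fat synthesis, glycolysis and cholangiocytes. Bile acid genes and stellate cell markers were lower too, but neither list stood apart at a pseudocount of 5. Among lists with a percentile, Kupffer cell markers had the highest median (0.78) and stellate cell markers the lowest (-1.01). Of 12905 compared genes, 691 (5.35%) were at least 2-fold higher in the HuR library and 1072 (8.31%) at least 2-fold lower. Genes at 0 in the β-Gal library were not listed, so genes found only in the HuR library could not count as higher. Another 8324 genes (64.5%) lay within 1.5-fold, and hepatocyte identity genes such as Alb, Hpx and Apoa1 were among them. Protein-coding genes made up 534 of the higher and 901 of the lower genes. Counting intervals lay wholly beyond 2-fold for 528 higher and 765 lower genes. At a threshold of 4-fold the balance turned, with 127 genes higher and 44 lower. The balance between directions depended on where the fold changes were centred, as the median log2 fold change of all compared genes was -0.17. Higher genes were 39.2% of calls as deposited and 59.3% (960 higher and 660 lower) once that median was set to 0. Removing the trend with GC content, or with GC content and length, gave 60.4% and 58.4% when the median was set to 0 as well, but 38.98% and 39.96% when it was kept.

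**Figure D1:**
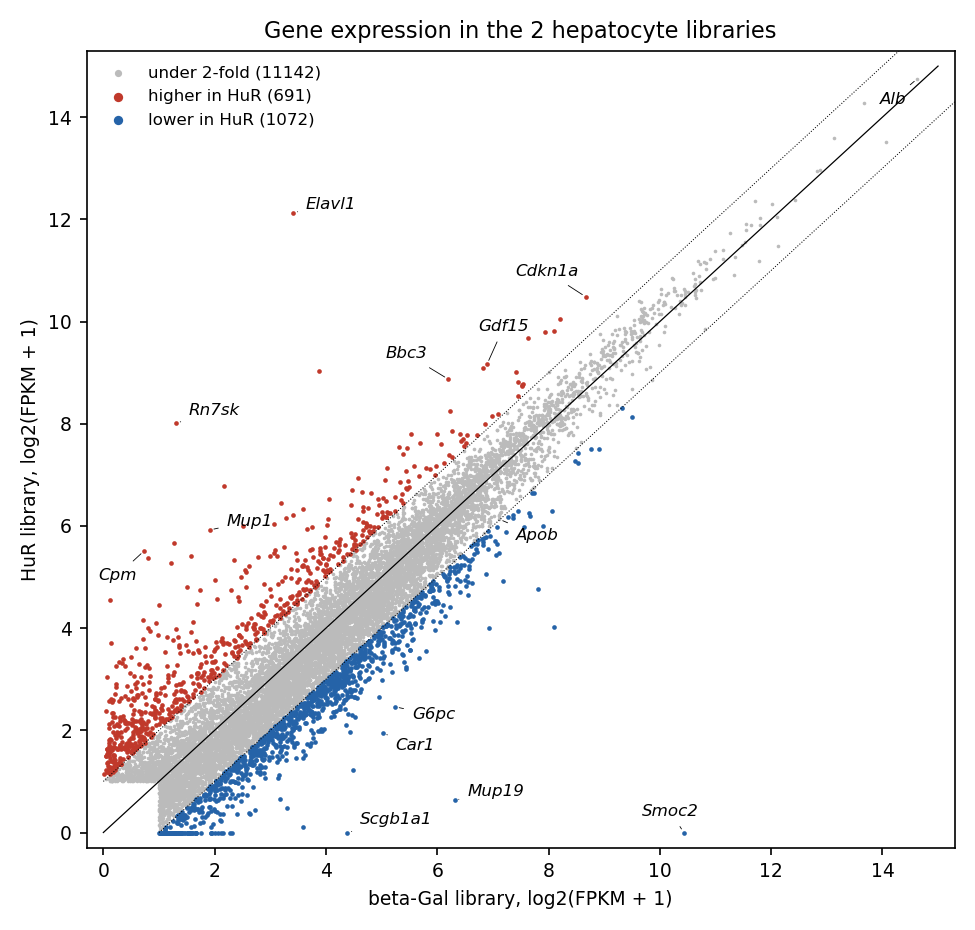
Expression of the 12905 compared genes in the β-Gal library (x axis) and the HuR library (y axis), each as log2(FPKM + 1), with 1 point per gene. Red points are the 691 genes at least 2-fold higher in HuR and blue points the 1072 at least 2-fold lower; the solid line marks equal values and dotted lines a 2-fold difference, with Elavl1 far above the line and Smoc2 at 0 in HuR.

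After Elavl1, the gene most above its control value was Rn7sk, the 7SK small nuclear RNA that restrains transcription elongation, at 1.48 FPKM in β-Gal and 257 FPKM in HuR (173-fold, 91.1 to 380). Rn7sk belongs to a list fixed as a sign of differences in library preparation and lies on chromosome 9 at 78175303 to 78175633. Cpm, a membrane carboxypeptidase, went from 0.661 to 44.6 FPKM (67.5-fold, 45.9 to 104), and Pld4, a phospholipase D family member, from 0.744 to 40.6 FPKM (54.6-fold, 33.9 to 97.4). Wfikkn1, a secreted protease inhibitor, stood at 1.42 and 49.8 FPKM, and Gzmm, a granzyme of cytotoxic lymphocytes, at 1.32 and 37.8 FPKM. St14, a membrane serine protease, went from 4.72 to 62.7 FPKM (13.3-fold, 11.3 to 15.6). Zfp365 stood at 1.00 and 20.8 FPKM, Ubap1l at 0.631 and 16.8 FPKM, and Ccdc154 at 0.0934 and 12.1 FPKM. Nme2, a nucleoside diphosphate kinase, was 20.8-fold higher (14.6 to 30.6), but its neighbour Nme1 begins 720 bases away and reads of the pair may not be fully separable. Mup1 was 21.5-fold higher, at 2.77 and 59.6 FPKM, and like other major urinary protein genes it has near-identical copies that make its value uncertain.

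Smoc2, a matricellular protein gene on chromosome 17 at 14279506 to 14404790, lay farthest below its control value. It stood at 1378 FPKM in the β-Gal library and 0 in the HuR library, at least 13494-fold lower against a floor of 3 reads, with a counting interval that began at 10974-fold. An exact 0 beside so high a value may be a failed estimate or an error in the table, and the values cannot separate this from a difference in transcript level. Mup19, also uncertain because of its paralogs, was 143-fold lower (78.5 and 0.549 FPKM). Airway and intestinal transcripts followed. The club cell secretoglobin Scgb1a1 went from 19.9 FPKM to 0 (at least 55.8-fold lower against that floor, with an interval from 44.9), and the surfactant gene Sftpc from 11.04 to 0.0704 FPKM. Reg3b, an intestinal antimicrobial lectin, was 15.9-fold lower (9.28 to 29.5), Muc2, the main intestinal mucin, 13.9-fold lower (7.95 to 26.6), and Lypd8 22.5-fold lower (11.2 to 52.9). Zg16 stood at 5.22 and 0.281 FPKM, the latter from 3 reads, and carbonic anhydrase Car1 at 31.5 and 2.85 FPKM. Among liver-expressed genes, G6pc, the catalytic subunit of glucose-6-phosphatase, was 8.19-fold lower (7.05 to 9.56), at 36.9 and 4.50 FPKM. Nbeal1 was 7.01-fold lower (6.09 to 8.08) and the nuclear import receptor Tnpo1 5.69-fold lower (5.11 to 6.34).

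Targets of p53 and apoptosis genes were higher in the HuR library. Of 27 compared members, 10 were at least 2-fold higher and 0 at least 2-fold lower. Their median log2 fold change was 0.65, above all 10000 random lists, and the list kept percentile 100 when random lists were also matched on GC content and length. Pmaip1, which encodes the pro-apoptotic protein NOXA, went from 0.741 to 14.9 FPKM (20.2-fold, 14.01 to 31.1). Bbc3, which encodes PUMA, went from 72.5 to 467 FPKM (6.45-fold, 6.07 to 6.86). The death receptor gene Fas stood at 11.6 and 60.2 FPKM, and the stress hormone gene Gdf15 at 118 and 573 FPKM. Cdkn1a, the cell cycle inhibitor p21, reached 1430 FPKM from 407 FPKM (3.52-fold, 3.44 to 3.60), and Mdm2, the ubiquitin ligase that limits p53, 232 FPKM from 75.5 FPKM (3.07-fold, 2.93 to 3.22). Cdkn1a and Mdm2 also belong to the list of mRNAs with reported HuR binding.

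**Figure D2:**
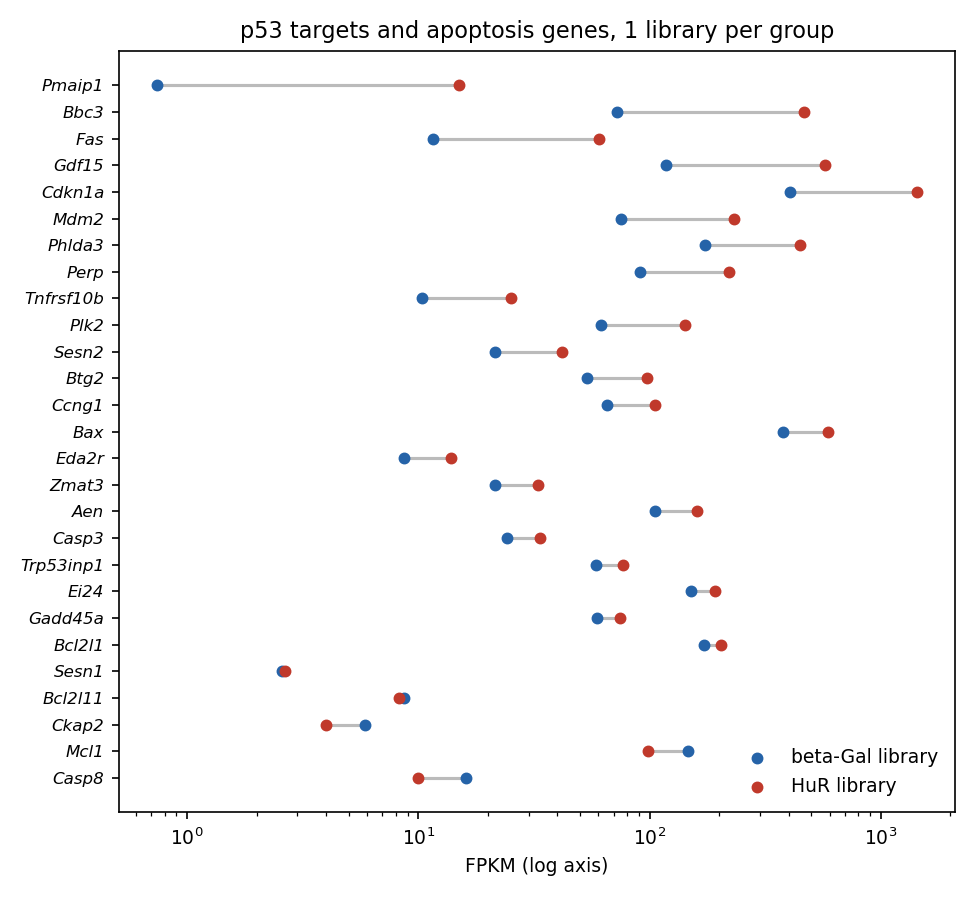
FPKM (log axis) of the 27 compared p53 target and apoptosis genes, with 1 blue point for the β-Gal library and 1 red point for the HuR library per gene, joined by a grey line and ordered by log2 fold change. In 10 genes, from Pmaip1 to Plk2, the red point lies at least 2-fold to the right; no gene lies 2-fold to the left.

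Of the other stress responses, heat shock and immediate early genes stood apart. Heat shock proteins were higher, with 4 of 16 members at least 2-fold higher, 1 lower and a median of 0.50 (percentile 100). The inducible chaperones Hspa1a and Hspa1b, near-identical copies, together went from 7.79 to 51.2 FPKM (6.57-fold), and the small heat shock protein Cryab stood at 3.03 and 9.31 FPKM. Hspa4l was the exception, 2.60-fold lower (2.33 to 2.91). Immediate early genes had 6 of 26 members higher, 1 lower and a median of 0.38 (percentile 100). Fos was 6.69-fold higher (5.26 to 8.60), Nr4a1 5.50-fold (4.59 to 6.62), Fosl1 4.22-fold (3.84 to 4.64) and Egr1 3.56-fold (3.24 to 3.92). The endoplasmic reticulum and amino acid stress list did not stand apart, with 2 of 28 members higher, 4 lower and a median of -0.19 (percentile 8.14). With the GC and length trends removed its median was 0.11 when the median of all genes was set to 0 and -0.06 when it was kept (percentile 79.25 in both). Within it Ppp1r15a, which restores translation after stress, was 4.03-fold higher and the glutathione-degrading enzyme gene Chac1 3.18-fold lower. NRF2 targets and glutathione genes also did not stand apart (2 of 26 higher, 1 lower, percentile 29.5), with heme oxygenase Hmox1 at 91.0 and 196 FPKM and Gstp1 at 8.78 and 21.1 FPKM.

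Inflammatory lists were split. Acute phase genes had a median of 0.34 (percentile 99.8), with 2 of 24 members at least 2-fold higher and 0 lower. Serum amyloid Saa4 was 3.36-fold higher (3.13 to 3.62) and the interleukin-1 receptor antagonist Il1rn 2.42-fold higher (1.85 to 3.18), while the iron hormone hepcidin (Hamp) stood at 1790 and 921 FPKM. With the GC and length trends removed, the acute phase list fell short of standing apart (percentile 98.5). NF-kB targets did not stand apart (percentile 81.4), with 3 of 21 higher and 1 lower: the cytokine Lif at 10.2 and 39.1 FPKM, the chemokine Cxcl2 at 8.58 and 30.9 FPKM, the adhesion molecule Icam1 at 60.9 and 127 FPKM, and the growth factor Csf1 at 71.1 and 29.6 FPKM. Interferon response genes were lower, with 0 of 42 members higher, 6 lower and a median of -0.43 (percentile 0.31). The viral RNA sensor Ddx58 was 3.12-fold lower (2.77 to 3.53), Ifi44 3.19-fold (2.63 to 3.88), Stat2 2.66-fold (2.37 to 2.98) and Parp14 2.42-fold (2.28 to 2.58). The interferon list reached only percentile 3.50 with the GC and length trends removed. Macrophage markers moved with the acute phase genes, at a median of 0.78.

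Fatty acid and triglyceride synthesis was the metabolic list with the lowest median. Of its 26 members, 9 were at least 2-fold lower and 1 higher, with a median of -0.80 that lay below all 10000 random lists under both ways of matching. Gpam, which starts glycerolipid synthesis, was 5.74-fold lower (4.98 to 6.62). Acaca, the acetyl-CoA carboxylase that commits carbon to fatty acids, was 2.71-fold lower (2.57 to 2.85), ATP citrate lyase (Acly) 2.47-fold lower (2.40 to 2.54) and malic enzyme Me1 2.33-fold lower (2.22 to 2.44). The phosphatidate phosphatase gene Lpin1 went the other way, 2.52-fold higher (2.27 to 2.81). Bile acid synthesis and transport had 4 of 18 members lower, 0 higher and a median of -0.62 (percentile 0.4). The bile acid receptor Nr1h4 was 5.36-fold lower (4.24 to 6.83), the conjugating enzyme Baat 4.41-fold (3.46 to 5.68) and the sterol hydroxylase Cyp8b1 3.39-fold (2.49 to 4.67), while Akr1d1 stood at 2.76 and 0.872 FPKM. The bile acid list no longer stood apart at a pseudocount of 5 (percentile 1.84).

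Other lipid lists did not stand apart. Cholesterol synthesis had 1 of 24 members lower (Idi1, 2.22-fold) and 0 higher (percentile 32.1). Fatty acid oxidation and ketone body synthesis had 3 of 29 lower and 0 higher (percentile 3.06). They included the nuclear receptor Ppara, 3.62-fold lower (2.60 to 5.13), and the carnitine palmitoyltransferase Cpt1a, 2.75-fold lower (2.33 to 3.25). Lipoprotein assembly and secretion had 1 of 23 lower and 0 higher (percentile 72.9), namely the cholesterol exporter Abca1 at 9.20 and 3.57 FPKM, while Apob stood at 137 and 69.3 FPKM.

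Glycolysis genes were lower as a list, with 2 of 22 members at least 2-fold lower, 0 higher and a median of -0.28 (percentile 0.67). The liver pyruvate kinase Pklr was 2.59-fold lower (2.52 to 2.66) and the hepatic glucose transporter Slc2a2 2.43-fold lower (2.30 to 2.57). Gluconeogenesis and glycogen had 3 of 17 lower and 0 higher (percentile 25.2), where G6pc was joined by the glucose-6-phosphate transporter Slc37a4 (3.02-fold, 2.68 to 3.40) and the glycogen branching enzyme Gbe1 (2.81-fold, 2.70 to 2.93). Urea cycle and amino acid catabolism went both ways, with 2 of 28 higher and 3 lower (percentile 27.2). Fah, the last enzyme of tyrosine breakdown, was 3.03-fold higher, and Cth, Dbt and the urea cycle enzyme Cps1 were 2.87-fold, 2.999-fold and 2.66-fold lower. The drug metabolism list had 8 of 44 lower, 0 higher and a median of -0.36 (percentile 0.39). The xenobiotic receptors Nr1i2 and Ahr were 3.12-fold and 2.68-fold lower, Cyp2c55 5.36-fold lower and the sulfotransferase Sult1d1 2.88-fold lower, but the list reached percentile 10.7 among lists also matched on GC content and length. Plasma protein and hepatocyte identity genes had 0 of 31 members past 2-fold either way (percentile 33.1), with Alb at 25353 and 27642 FPKM and hemopexin (Hpx) at 3582 and 3803 FPKM. The lowest log2 fold changes in that list were those of the transcription factors Nr5a2 (-0.93), Foxa3 (-0.88) and Onecut1 (-0.71), named here after their values had been seen. Nr5a2 stood at 11.8 and 5.71 FPKM, Foxa3 at 19.98 and 10.4 FPKM, and Onecut1 at 1.24 and 0.372 FPKM (3.34-fold lower, 1.92 to 6.11).

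Markers of other liver cell types did not move together. Kupffer cell and macrophage markers were higher, with 4 of 18 at least 2-fold higher, 0 lower and a median of 0.78 (percentile 100). The scavenger receptor Marco stood at 5.55 and 14.8 FPKM, the complement genes C1qb at 2.503 and 6.97 FPKM and C1qc at 2.28 and 6.32 FPKM, and Cd68 at 40.0 and 90.4 FPKM. Stellate cell and fibroblast markers were lower, with 5 of 8 lower, 1 higher and a median of -1.01 (percentile 0.09), but not apart at a pseudocount of 5 (percentile 1.33). The collagens Col3a1 and Col1a1 were 8.32-fold (4.77 to 15.7) and 9.82-fold (5.13 to 21.1) lower at under 4 FPKM, smooth muscle actin Acta2 was 21.8-fold lower (6.99 to 224), and Ecm1 was 2.33-fold higher. Cholangiocyte markers had 5 of 12 lower, 1 higher and a median of -0.74 (percentile 0.28), with Cldn7 at 2.31 and 0.137 FPKM, Epcam at 2.14 and 0.194 FPKM, and Krt7 higher at 0.199 and 2.76 FPKM. Markers of smooth muscle and of intestine were lower in the HuR library as well: summed reads per library total in the β-Gal library were 1.75 times (1.55 to 1.97) and 2.32 times (2.12 to 2.55) those of the HuR library. Leaving out 1 marker at a time gave 1.34 (without Hspb6) to 3.05 (without Smtn) for smooth muscle and 2.14 (without Lgals4) to 4.50 (without Ces1f) for intestine. Endothelial markers had 2 of 11 higher, Eng and Stab1, and 0 lower by the 2-fold rule with the pseudocount (percentile 96.4). Flt4, the receptor of lymphatic growth factors, nevertheless stood at 3.87 and 1.54 FPKM, 2.51-fold lower without the pseudocount (2.05 to 3.09). Only 4 lymphocyte, neutrophil and blood markers were compared, of which 3 were lower: the immunoglobulin gene Igkc at 5.43 and 0.851 FPKM, and the globins Hbb-bs and Hba-a1, at 2.17 and 1.55 FPKM in β-Gal and at least 5.87-fold and 5.46-fold lower against the floor, with intervals from 4.23 and 3.97.

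The mRNAs with reported HuR binding did not stand apart as a list. Of 43 compared members, 5 were at least 2-fold higher and 4 lower, with a median of -0.12 (percentile 21.5, or 62.1 among lists also matched on GC content and length). The sign of that median turned with the GC and length trends removed, to 0.20 with the median of all genes set to 0 and 0.03 with it kept (percentile 97.55 in both), and to 0.05 with that median set to 0 alone. Fos, Cdkn1a and Mdm2 were among the higher members, as was the transcription factor Snai1, 12.1-fold higher (7.11 to 21.99) at 0.504 and 6.07 FPKM. AU-rich element binding proteins had 2 of 17 higher and 3 lower (percentile 46.5). Apart from Elavl1 itself, the splicing regulator Ptbp1 was 2.26-fold lower (2.14 to 2.39) and Hnrnpd 2.16-fold (1.98 to 2.36). Cell cycle genes had 4 of 33 higher and 2 lower (percentile 76.5), with the replication genes Cdt1, Mcm7 and Rrm2 at 2.54-fold, 2.39-fold and 2.30-fold higher and Ccnb2 at 1.03 and 3.75 FPKM. Among cell cycle members with at least 10 FPKM in a library, the list stood apart at percentile 99.9.

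Ribosomal proteins had 1 of 74 members past 2-fold (Rps27, 182 and 430 FPKM) and a median of 0.29 (percentile 99.9), with abundant members such as Rps2 at 2251 and 2704 FPKM. Nuclear-encoded oxidative phosphorylation genes had 1 of 76 higher (Uqcrc1, 13.9 and 42.8 FPKM), 1 lower (Ndufs1, 52.1 and 16.9 FPKM) and a median of 0.22 (percentile 99.2). With the GC and length trends removed, these lists stood at percentiles 59.8 and 82.5, and with the median of all genes kept their medians turned to -0.04 and -0.05. Mitochondrially encoded genes had 0 of 13 past 2-fold (percentile 34.2, or 99.6 with those trends removed), with mt-Co1 at 7551 and 7964 FPKM. Proteasome subunits had 0 of 31 past 2-fold (percentile 52.4), with Psmd8 at 739 and 883 FPKM. Spliceosome and nuclear RNA-binding proteins had 4 of 42 lower and 0 higher (percentile 8.62), including Srsf11 and Hnrnpdl at 2.43-fold and 2.35-fold lower.

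The lists of nuclear-retained and non-coding RNAs and of histones had been fixed as signs of differences in library preparation, and Rn7sk, Rpph1 and most replication-dependent histone mRNAs lack a poly(A) tail. Nuclear-retained and non-coding RNAs had 3 of 8 higher, 1 lower and a median of 0.58 (percentile 99.8), but percentile 94.2 among members with at least 10 FPKM. Beside Rn7sk, the snoRNA host gene Snhg1 was 4.77-fold higher (4.36 to 5.23) and the RNase P RNA Rpph1 3.71-fold higher (2.02 to 7.27), while the nuclear RNA Malat1 was 2.33-fold lower (2.26 to 2.40). Replication-dependent histones had 3 of 8 higher and 0 lower (percentile 97.0), all from few reads, such as Hist1h4d at 0.554 and 2.45 FPKM. Matrix and cytoskeleton genes of cultured hepatocytes had 0 of 32 past 2-fold and a median of -0.13 (percentile 0.57, or 1.74 among lists also matched on GC content and length; 0.03 with the median of all genes set to 0), with fibronectin (Fn1) at 385 and 199 FPKM. Clock genes had 3 of 18 lower and 0 higher (percentile 5.86): Clock was 4.11-fold lower (3.42 to 4.96), Hlf 4.06-fold (2.82 to 5.98) and Bhlhe40 2.16-fold (2.07 to 2.26). Growth hormone-regulated and sex-biased genes had 3 of 27 higher and 2 lower (percentile 56.4), among them Mup17 at 169 and 518 FPKM, Mup11 at 187 and 61.9 FPKM, and the cytokine signalling inhibitor Cish at 3.59 and 8.69 FPKM.

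**Figure D3:**
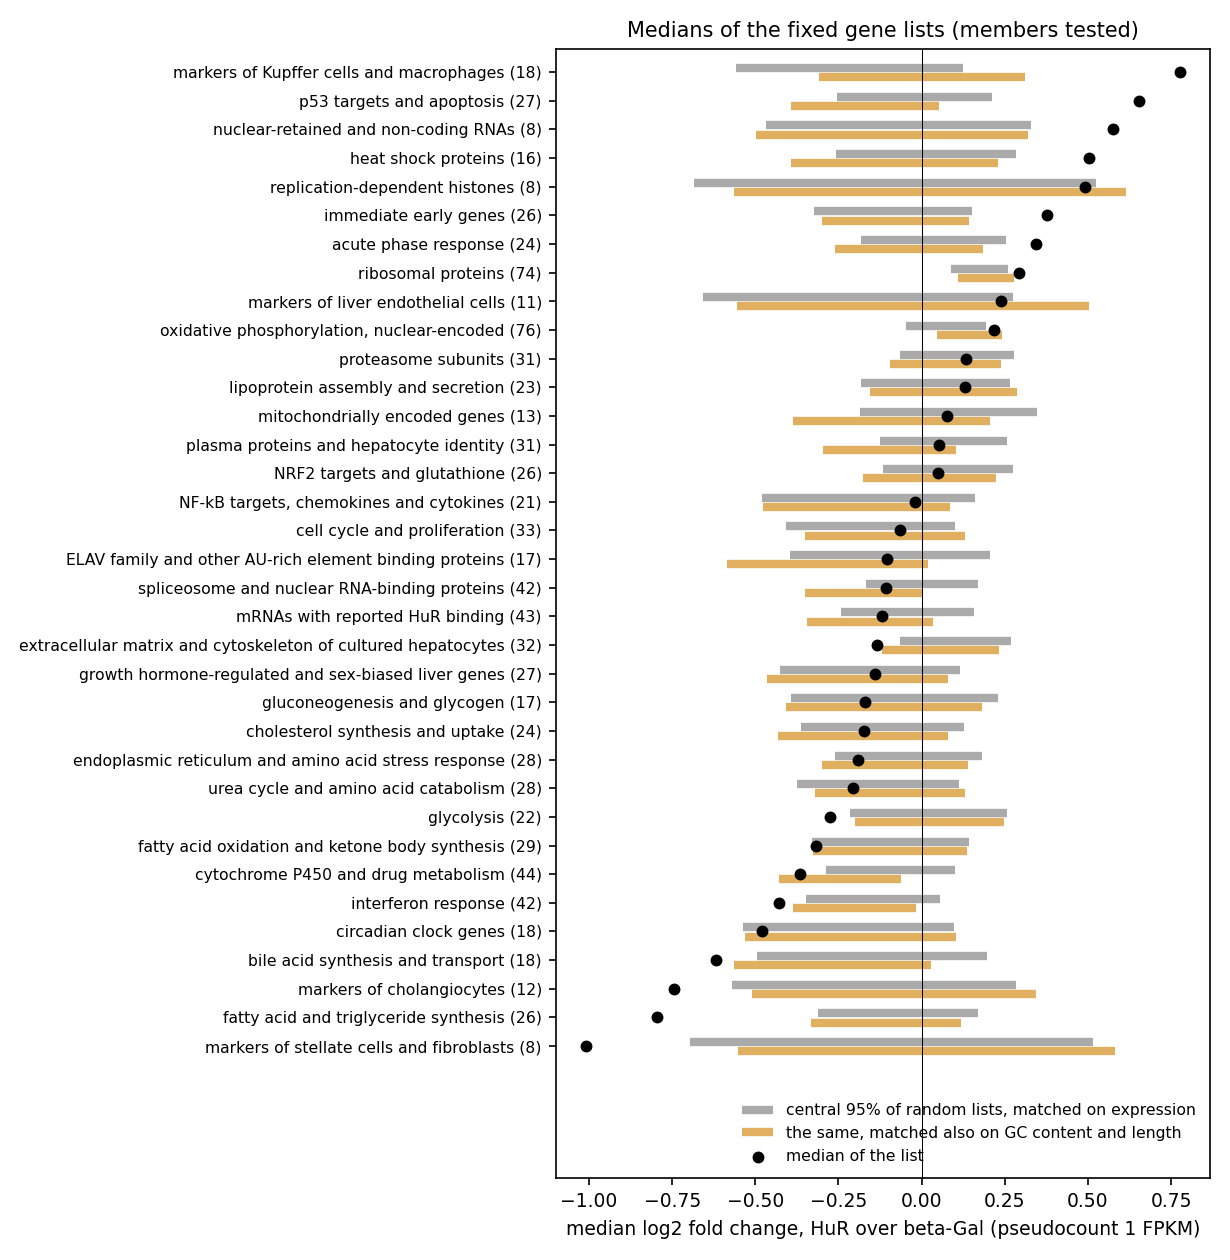
Median log2 fold change (HuR over β-Gal, pseudocount 1 FPKM) of the 35 lists with a percentile, each as a black point, with the number of compared members after its name. Grey bars span the central 95% of 10000 random lists matched on expression and orange bars the same with GC content and length matched too; Kupffer cell markers (0.78) and p53 targets (0.65) lie farthest right, and stellate markers (-1.01) and fat synthesis (-0.80) farthest left.

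Of the 35 lists with a percentile, 8 stood apart on the high side and 8 on the low side. The percentile bounds alone would give 0.7 for lists of unrelated genes, and 3% of simulated random lists fell beyond them. The lists share genes and may move together within 1 pair of libraries, so this number is no test of the lists. Matching on GC content and length as well left 7 and 6. Long and AU-rich transcripts were lower in the HuR library across protein-coding genes. The median log2 fold change went from -0.52 in the decile of lowest GC content to 0.16 in the highest, and from 0.21 in the shortest decile of transcripts to -0.46 in the longest. Across genes, which are not independent replicates, the fold change had a Spearman correlation of 0.35 with GC content and -0.32 with length. Higher genes had a median GC content of 54.7% and lower genes 46.2%, against 50.3% in all compared genes.

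**Figure D4:**
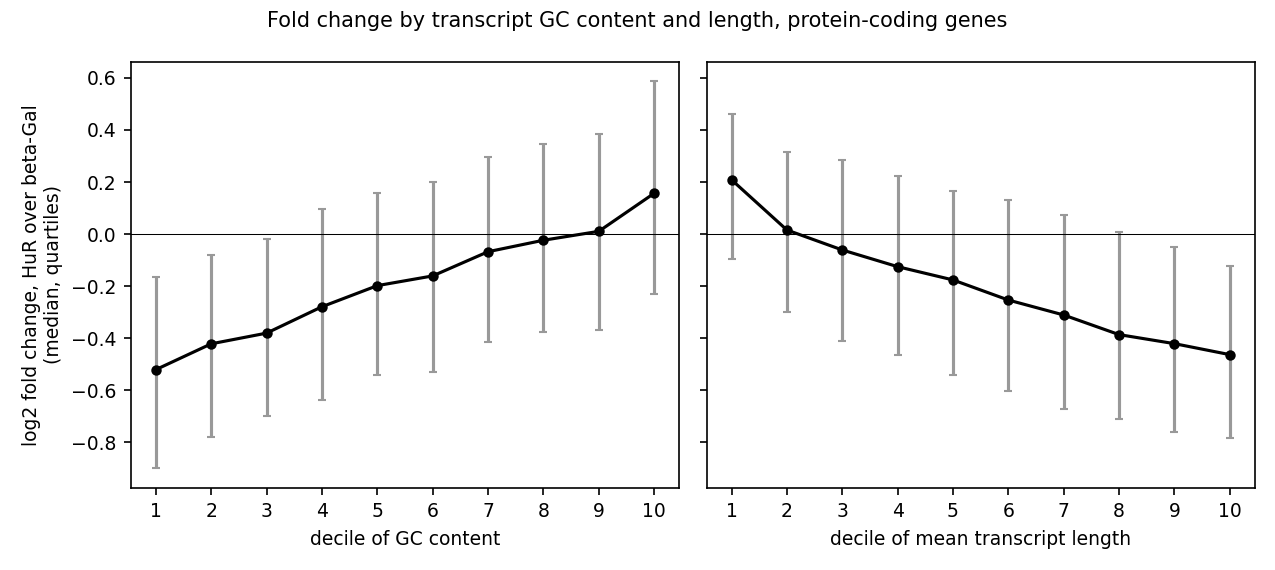
Median log2 fold change (HuR over β-Gal) of protein-coding genes in deciles of transcript GC content (left) and mean transcript length (right), with grey bars from the lower to the upper quartile of genes. Medians go up with GC content, from -0.52 to 0.16, and down with length, from 0.21 to -0.46.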

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

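The alternatives that removed the GC content and length trends, set the median of all genes to 0, asked for 100 reads or for a counting interval beyond 2-fold, and matched random lists on GC content and length were chosen after the data had been seen. No paired analysis was possible because each group had 1 library and the labels carry no shared replicate numbers, and for the same reason no library could be left out. As reported, 691 genes were higher and 1072 lower. A pseudocount of 0.1 gave 1762 lower genes, and a pseudocount of 5 gave 260 higher and 330 lower. A minimum of 10 FPKM left 7489 genes, of which 332 were higher and 600 lower. A threshold of 1.5-fold gave 1555 higher and 3026 lower genes, and a threshold of 4-fold gave 127 and 44, so the majority was higher at that size; a stricter or looser rule changes counts by construction. Setting the median of all genes to 0 gave 660 lower genes. Removing the GC trend, which sets that median to 0 too, gave 553, and removing the GC and length trends 557, of which 490 were among the 1072; with the median kept these were 947 and 870. The Elavl1 log2 fold change was 8.71 as reported, 8.84 and 8.26 with pseudocounts of 0.1 and 5, 9.13 and 9.24 with the GC trend and with both trends removed, 8.96 and 9.08 when the median was kept, and 8.88 with the median set to 0 alone. Counts under the other alternatives stayed within 1.5 times. Rescaling shifted the ratio of the libraries by between -0.07 and 0.07 on the log2 scale before the pseudocount was added. On the TPM scale, where the pseudocount weighs less and more genes pass the minimum, values could move further. Lower genes numbered 1513 there, and the bile acid median went from -0.62 to -0.75. Removing the expression minimum added no call because the pseudocount keeps genes under 1 FPKM below 2-fold. The number of lists standing apart ranged from 12 to 18, against 16 as reported; the 18 on the TPM scale included lymphocyte and blood markers (percentile 0.34), which had too few members for a percentile as reported, and 4 lists had too few at 10 FPKM. The p53, heat shock, immediate early, Kupffer cell, fat synthesis, glycolysis and cholangiocyte lists stood apart under every alternative run. Interferon genes did not without an expression minimum (percentile 1.09) or at 10 FPKM (1.59), nor acute phase genes at 10 FPKM (97.9), nor oxidative phosphorylation under median centring (98.96). Without a minimum, stellate markers (2.98), matrix genes (1.04) and nuclear RNAs (98.04) no longer stood apart, while histones (99.92) and endothelial markers (99.51) did, as did histones on the TPM scale (99.83) and fatty acid oxidation at a pseudocount of 5 (0.89). The cause was not tested. A list median cannot change where only the matching of random lists differed. With those values counted in, 388 of 416 list medians under alternatives stayed within the interval of the median as reported, 25 moved and 3 reversed. The 3 were ribosomal proteins (-0.040) and oxidative phosphorylation (-0.047) with both trends removed and the median kept, and matrix genes (0.032) with the median set to 0. Lists that had not stood apart changed sign in 25 values. With both trends removed, 8 such lists turned positive: HuR-bound mRNAs (0.20), AU-rich element binding proteins (0.15), endoplasmic reticulum stress (0.11), spliceosome (0.10), sex-biased genes (0.09), cell cycle (0.08), NF-kB targets (0.07) and cholesterol synthesis (0.05). With the median kept, only HuR-bound mRNAs of these did (0.03). NRF2 targets (-0.11), hepatocyte identity (-0.03), lipoprotein assembly (-0.01) and proteasome subunits (-0.002) then turned negative. A named gene counted as moved when its log2 value shifted by more than the distance from the middle to the end of its counting interval. Genes without HuR reads had an interval open at its lower end, so they could hardly count as moved. By this rule 1230 of 1760 values of named genes stayed and 530 moved, with 0 called genes reversed. Reversal was counted only for genes at least 2-fold apart, whose sign a change of pseudocount or scaling could hardly turn, so this 0 says little. Genes of low expression rest on few reads, and the effect of depth was not tested. Higher genes had a median of 290 reads over both libraries and lower genes 676.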

Other observations

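In this part, the tests of interferon genes as a sign of the adenovirus, of intestine and lung markers one by one or with many reads, of sums without 1 marker, and of slopes at matched expression were chosen only after the result was seen. Major urinary protein genes, which liver secretes as pheromone carriers, differed little in total while single copies diverged. The 19 protein-coding Mup genes summed to 1628 FPKM in the β-Gal library and 2071 FPKM in the HuR library (1.27-fold), although Mup1 was 21.5-fold higher and Mup19 143-fold lower. Cpm, 67.5-fold higher, ends 1523 bases from Mdm2 on chromosome 10, and Mdm2 was 3.07-fold higher. Smoc2, at 1378 and 0 FPKM, is given here as a value only, beside the collagen Col1a1 at 3.12 and 0.318 FPKM.

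Transcripts typical of intestine and lung were mostly higher in the β-Gal library. Beside Scgb1a1, Sftpc, Reg3b and Muc2, 39 further markers of these tissues were fixed before their values were seen, and 36 of them were higher in the β-Gal library. The exceptions were Ces1f, which liver also expresses (272 reads against 370 in the HuR library), Ager (34 against 113) and Scgb3a1 (5 against 5). Lgals4 had 355 reads against 105, Muc13 107 against 4, Reg3g 112 against 7, and Agr2 52 against 0. Of 9 listed smooth muscle markers, 7 were higher in the β-Gal library, and their summed reads relative to the library total were 1.75 times those of the HuR library (1.55 to 1.97), from 1.34 without Hspb6 to 3.05 without Smtn. Only 39 of 89 markers fixed for 7 control tissues were listed, against all of those for intestine and lung. Of the 39 listed control markers, 25 were also higher in the β-Gal library. Summed reads were higher there for brain (1.51 times, 1.22 to 1.87, or 2.14 without Mbp) and striated muscle (2.07, 1.41 to 3.09). The latter rested on Acta1 (1.54, 0.912 to 2.65 without it), and was 3.29 without Tnnt2. Sums were lower for skin (0.399, 0.376 to 0.422), pancreas (0.447, 0.345 to 0.576), kidney (0.166, 0.0502 to 0.434) and stomach (0.224, 0.124 to 0.384). Kidney rested on 2 listed markers with 5 reads against 29 in the HuR library, and stomach on 3 with 17 against 73. Testis stayed open (2.20, 0.856 to 6.32).

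Reads from intestine and lung tissue in the β-Gal library are a candidate explanation, and marker by marker the median β-Gal to HuR ratio was 6.97 (bootstrap interval 4.15 to 8.66), against 2.06 (0.963 to 2.89) for the control markers. Summed over the 39 markers, the ratio was 2.22 (2.04 to 2.40), or 3.34 (3.02 to 3.69) without Ces1f, with intestine at 2.32 (2.12 to 2.55; 2.14 without Lgals4 and 4.50 without Ces1f) and lung at 1.90 (1.61 to 2.24; 3.57 without Ager and 1.46 without Reg3g), so neither bound set in advance, at least 3 in both tissues or under 2 in both, was met. The omission of genes at 0 in the β-Gal library is argued against as the whole cause. It hardly touches markers with at least 20 reads over both libraries. For 25 such intestine and lung markers the median was 6.97 (bootstrap interval 3.24 to 9.11), against 0.79 (bootstrap interval 0.215 to 1.51) for 15 control markers. The control tissues together summed to 0.45 (0.427 to 0.474), or 0.658 without Krt5 (1494 and 3628 reads), but brain lay above 1, as did striated muscle only with Acta1, so a part played by omission at few reads, or by reads of further tissues, stays open. No biological explanation was tested, and whether such reads entered the library stays open.

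Long transcripts of low GC content were lower in the HuR library, for which a GC content and length bias between the libraries may account, in which case long non-coding RNAs would follow the same trend as mRNAs. Intervals in this paragraph are bootstrap intervals from genes resampled within the 2 libraries, and leave out differences between cultures or preparations. Over 416 such RNAs the slope on GC content was 0.385 times that of protein-coding genes (0.0209 to 0.788). At matched expression it was 0.31 times (0.0209 to 0.635). The slope per doubling of length was -0.030 (-0.101 to 0.041), against -0.14 (-0.18 to -0.10) in protein-coding genes at matched expression. That was a ratio of 0.211 (-0.274 to 0.746). An equal trend in both kinds of RNA lay outside these intervals for GC content and for length. But the RNAs include antisense and intronic transcripts, and without a strand setting their reads may come from overlapping mRNAs. The comparison therefore cannot decide on an equal trend. The intervals also span the bounds for and against, and a weaker bias cannot be told apart from an effect on mRNAs. Loss of mRNAs through AU-rich 3' UTRs is the other candidate: the slope on 3' UTR GC content was 0.453 times that on the rest of the mRNA (0.336 to 0.6002), below the equal slope this explanation called for, yet with an interval that crossed the bound set for rejecting it. Both stay open, and with 1 library per group HuR itself is tied to the preparation.

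Targets of p53 were higher in the HuR library, and a GC content or length bias is argued against, since the list stood at percentile 100 of random lists matched on expression, GC content and length. A larger response to the adenovirus is argued against only as far as interferon genes report it, since that list stood at percentile 0.72 of equally matched lists. With the GC and length trends removed it stood at percentile 3.50. Heat shock, immediate early and acute phase genes stood apart on the high side, so a response to the virus through other genes stays open. Differences between cultures or virus preparations stay open, because each condition was a single library. An effect of HuR on this pathway may be considered only as a hypothesis.

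Higher levels of mRNAs with AU-rich or U-rich motifs in the 3' UTR, as stabilisation by HuR might give, were looked for and not seen. At matched expression, GC content and length, genes with 3 or more ATTTA motifs in the 3' UTR differed from genes with none by -0.028 in median log2 fold change (bootstrap interval -0.069 to 0.014), whereas without matching the difference was -0.39. Genes in the upper tertile of U-rich motif density differed from those in the lower tertile by -0.031 (-0.069 to 0.006), and by -0.26 without matching. Both upper bounds lay under the difference set in advance for this hypothesis. Motif counts are not measured binding sites, and FPKM values do not measure decay. Matching on GC content and length may also remove part of an effect that goes with AU-rich sequence. Stabilisation of bound mRNAs itself was therefore not tested.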
